A study of Homo sapiens with 6 samples.

How the data were processed

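Messenger RNA was measured in RCC10, an established line of clear cell renal carcinoma that is VHL-deficient per the labels. The labels give 3 groups of 2 libraries: parental cells, cells in which HIF-1alpha and HIF-2alpha were knocked out with lentiviral guide RNAs and puromycin selection, and cells given a lentivirus carrying VHL. Cells were grown in DMEM with 10% fetal bovine serum, and libraries came from column-purified, DNase-treated RNA with poly(A) selection, per the labels. Whether the knockout cells were a clone or a pool, and whether the replicates of a group were separate cultures, is not given in the sources used here.

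The authors deposited one table of counts, with whole-number reads for 19009 gene symbols in 6 columns. Per the submitters' processing notes, FastQC 0.74, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.8 and limma 3.58.1 were used, without their order or settings. The notes name the genome builds hg38 and hg19 without saying which the counts use, so no coordinates are printed here. Strandedness and the counting settings, including how reads shared between near-identical genes were handled, are not given in the sources used here. Values of histone, UGT1A, AKR1C and ribosomal protein genes and of SLC2A3 are uncertain for that reason.

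The table's name calls the values normalized, but they are whole numbers, each small integer occurs, and the column totals differ, so they were treated as raw counts. The plan written before the data were examined expected log2 values and a limma fit, and named edgeR's quasi-likelihood test for the case of whole counts, which is what was used. Of the 19009 genes, 18273 with at least 1 count in some library were tested. Library scaling was by TMM, with factors from 0.977 to 1.02. Dispersions and the quasi-likelihood fit used all 6 libraries in a model of 3 group means, with edgeR 4.0.16 in R 4.3.3, prior count 0.125, and Benjamini-Hochberg adjustment per comparison at 0.05. The common dispersion was 0.00194, a biological coefficient of variation of 4.41%. Levels are CPM, counts scaled to the TMM library size, given as mean ± SD of 2 libraries, and the SE of a log2 fold change is the Wald error from the same fit.

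Total counts per library were 29454611 and 22248126 (parental), 29929116 and 26085121 (double knockout), and 27890958 and 27776717 (VHL-restored). A floor of 3 counts corresponds to 0.100 to 0.135 CPM in a single library. Where a group had no count, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. These intervals and floors cover counting error only. Replicates of a group varied more than counting error, with a chi-square per degree of freedom of 2.58 (parental), 4.67 (double knockout) and 6.61 (VHL-restored) over genes with at least 10 counts.

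The comparisons were double knockout with parental, VHL-restored with parental, and double knockout with VHL-restored, which tests the difference between the engineered lines. The overlap of the first 2 comparisons was set beside independent lists and beside 20 simulations of unchanged groups. In these the counts of all 6 libraries, parental ones included, were drawn from the parental means. The analysis was tested on simulated data, with all counts drawn anew from the mean levels of the libraries and the fitted dispersions. In a single draw per comparison, 50 genes at each of 4 sizes of change were altered. These 200 genes are far fewer than the 9888 called in double-knockout cells. Adjustment for multiple testing is then stricter, so the shares below may understate recovery of small changes in the data. In double knockout against parental cells 14%, 84%, 98% and 100% of genes changed by 1.2, 1.5, 2 and 4-fold were recovered, with 0% false calls. The matching shares were 34%, 92%, 100% and 100% with 4.12% false calls in VHL-restored against parental cells, and 36%, 98%, 100% and 100% with 2.34% false calls between the engineered lines.

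The 34 gene lists were written before the data were examined. Of their 833 members 794 were matched to the table. Of the table's symbols 16912 are current, 1383 are older symbols of one gene and 714 are neither. Of the lists, 33 were tested, and the mitochondrially encoded messenger RNAs were not analysed here because the table holds 0 of the 13. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Members past 0.05 were counted with adjustment over all genes, and with adjustment over the list alone.

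Genes are named in the text by a rule fixed before the data were examined. It takes HIF1A, EPAS1, ARNT and VHL, then for each comparison the 10 genes most raised and the 10 most lowered among those past 0.05 with replicates that do not overlap, then up to 4 members of each list with the largest change, or the 2 with the smallest p where none passed. The genes of the on and off pattern and the gene families in the last part were chosen after their values were seen. CSF1R is named as a leukocyte marker above 1 CPM, also after its value was seen.

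Alternatives planned before the data were examined were a constant dispersion in place of a trend, median centring, quantile normalization, a filter on mean log2 CPM under 1, a larger pseudocount, replicate number as a block, fits of 2 groups alone, leaving out each library, sample weights, a change of at least 2-fold, and DESeq2 1.42.0. The pseudocount, quantile and sample-weight alternatives were run in limma on log2 CPM. Alternatives chosen after seeing the data were limma on log2 CPM (prior count 2), median-ratio size factors in edgeR, a correction for GC content and transcript length (loess span 0.3), and removal of the median of the 40 nearest expressed genes. GC content and length came from the longest GENCODE v29 transcript, for 95.1% of tested genes. Gene order came from the RefSeq GRCh38.p14 annotation, for 96.3%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 6 columns of the table were used, and 736 genes without a count were left out.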

Results

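Poly(A)-selected RNA was sequenced from RCC10, an established human clear cell renal carcinoma line that lacks functional VHL. VHL is the substrate-binding part of the ubiquitin ligase that marks the HIF alpha subunits for degradation when oxygen is present. The 6 libraries form 3 groups of 2: parental cells, cells in which both HIF1A and EPAS1 (the gene of HIF-2alpha) were targeted by guide RNAs (HIF double-knockout cells), and cells given a lentivirus carrying VHL (VHL-restored cells). Total counts ranged from 22248126 to 29929116 per library, with 29454611 and 22248126 in parental, 29929116 and 26085121 in double-knockout, and 27890958 and 27776717 in VHL-restored cells. Of 19009 genes, 18273 had at least 1 count in some library and were tested. FN1, encoding the matrix protein fibronectin, had the most counts in each library, with 2.42% and 2.34% of the total in parental, 4.57% and 4.42% in double-knockout and 7.62% and 6.85% in VHL-restored cells. Spearman correlation across genes, which are not independent replicates, was at least 0.992 between replicates and at most 0.965 between libraries of different groups. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

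The targeted genes were examined first, in every library. EPAS1 fell 7.60-fold in double-knockout cells, from 350.5 ± 2.21 to 46.2 ± 2.54 CPM (counts scaled to library size, mean ± SD, n = 2), with a log2 fold change of -2.92 ± 0.06 (SE, adjusted p = 1.2e-26, edgeR). HIF1A fell 2.33-fold in the same cells, from 71.2 ± 2.42 to 30.6 ± 1.42 CPM (adjusted p = 1.1e-15, edgeR). Both transcripts thus remained in double-knockout cells. Transcript level does not show whether HIF-1alpha or HIF-2alpha protein was lost, and the counts hold no measure of protein. VHL rose 17.6-fold in VHL-restored cells, from 39.1 ± 0.461 to 687 ± 50.3 CPM (adjusted p = 3.7e-29, edgeR), and the table does not separate the introduced from the resident transcript. HIF1A mRNA also rose in VHL-restored cells, 4.15-fold to 295.2 ± 12.6 CPM, whereas EPAS1 was 366.1 ± 4.78 CPM with a log2 fold change of 0.06 ± 0.06 that did not pass (adjusted p = 0.386, edgeR). Under median centring EPAS1 passed, at 0.15 on the log2 scale (adjusted p = 0.0334, edgeR). ARNT, the shared dimerization partner of both HIF alpha subunits, fell by 0.39 on the log2 scale in double-knockout cells and by 0.17 in VHL-restored cells (adjusted p = 1.7e-05 and 0.0338, edgeR). The ARNT call in VHL-restored cells was lost without parental replicate 1, parental replicate 2 or VHL-restored replicate 1, with adjusted p between 0.107 and 0.231. In double-knockout cells VHL was 45.3 ± 2.87 CPM, a log2 fold change of 0.21 ± 0.07 (adjusted p = 0.0143, edgeR) whose call was lost without parental replicate 1, parental replicate 2 or double-knockout replicate 2 (adjusted p between 0.119 and 0.213).

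**Figure D1:**
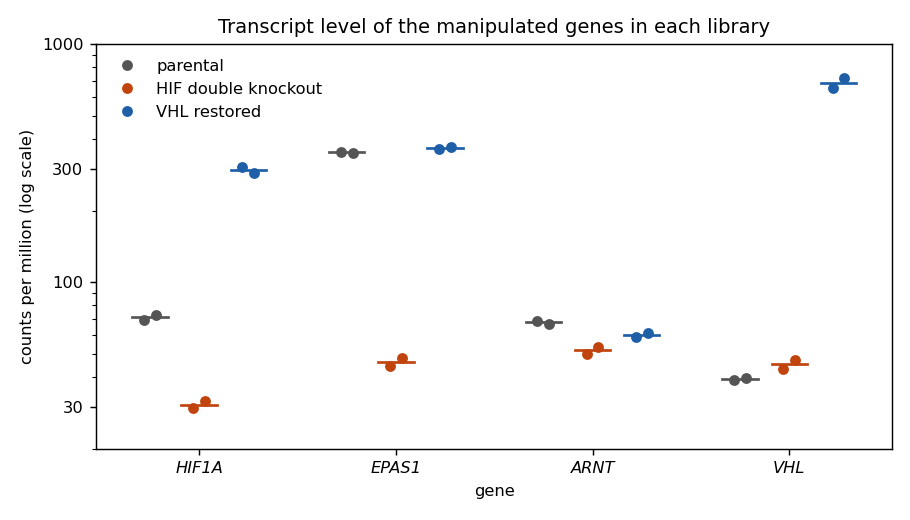
Level of HIF1A, EPAS1, ARNT and VHL in each of the 6 libraries, in CPM on a log axis, by group, with bars at the group means. VHL stands at 687 CPM in VHL-restored against 39.1 in parental cells, and EPAS1 at 46.2 CPM in double-knockout against 350.5 in parental cells.

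The comparison of double-knockout with parental cells asked which transcripts differed after HIF1A and EPAS1 were targeted. None of the groups had a non-targeting guide RNA or an empty vector. Effects of lentivirus, selection or cell population therefore cannot be told apart from those of losing HIF. Single HIF-responsive transcripts fell far: EGLN3, an oxygen-sensing prolyl hydroxylase, fell 1136-fold from 418 ± 0.478 to 0.358 ± 0.122 CPM (n = 2), and NDRG1, a stress-responsive gene, fell 50.1-fold from 1808 ± 73.9 to 36.1 ± 1.14 CPM. STC1, encoding the secreted hormone stanniocalcin, was at 26.8 ± 3.72 CPM in parental cells and had no count in double-knockout cells, a change of at least 497-fold lower. IGFBP3, an insulin-like growth factor binding protein, fell 30.6-fold from 3503 ± 24.2 CPM, and PLIN2, the coat protein of lipid droplets, fell 17.2-fold from 943 ± 9.27 CPM. In the other direction SERPINB2, a serine protease inhibitor, went from 0.0221 to 383 ± 36.9 CPM, a ratio of 20140 with a counting interval of 3615 to 795600, and the cytokine gene IL6 rose 44.8-fold from 1.79 ± 0.283 to 81.4 ± 1.96 CPM.

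Of 37 genes widely used as readouts of hypoxia, 33 fell, 2 rose and 2 did not pass, with the same 33 and 2 when adjusted over the list alone. Their median log2 fold change was -1.80 (-1.72 with bounds), and the list was lower than other genes by camera (adjusted p = 2.0e-14, and adjusted p = 0.274 with an estimated correlation). Medians with bounds, here and below, set genes with no count in 1 group to their bound. They leave out genes with at most 3 counts in both groups, so they may rest on fewer genes than the list. Besides EGLN3 and NDRG1, PPFIA4 fell by 5.55 ± 0.22 (SE) on the log2 scale. Of 16 genes linked to HIF-2alpha in clear cell renal carcinoma, 12 fell, 2 rose and 2 did not pass (12 and 2 adjusted over the list alone, median -2.16, -2.23 with bounds). By camera the HIF-2alpha-linked list had adjusted p = 4.7e-05, and adjusted p = 0.362 with an estimated correlation. Among them MMP2, a matrix metalloproteinase, went from 11.9 ± 1.49 to 0.0536 CPM, a ratio of 219.9 with a counting interval of 74.9 to 1069. CXCR4, a chemokine receptor, was at least 27.3-fold lower, from 1.48 ± 0.0982 CPM to no count.

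Glucose metabolism moved the same way. Of 23 genes of glucose uptake and glycolysis 17 fell, 1 rose and 5 did not pass (17 and 1 adjusted over the list alone, median log2 fold change -0.83). By camera the glycolysis list had adjusted p = 1.1e-06, and adjusted p = 0.475 with an estimated correlation. ALDOC, an aldolase, fell 10.8-fold, PDK1, the kinase that restrains pyruvate dehydrogenase, fell 8.29-fold, PFKFB4, a regulator of phosphofructokinase, fell 7.76-fold, and SLC2A3, a glucose transporter, fell 7.71-fold from 135.8 ± 8.37 CPM. Reads of SLC2A3 and its near copy SLC2A14 may have been split in counting. Nuclear genes of the respiratory chain and ATP synthase rose more often than they fell, with 51 of 74 higher, 5 lower and 18 not passed (53 and 5 adjusted over the list alone, median 0.28). By camera the respiratory chain list had adjusted p = 3.2e-06, and adjusted p = 0.725 with an estimated correlation. UQCRFS1, the iron-sulfur subunit of complex III, rose 2.33-fold from 58.6 ± 1.97 to 136.9 ± 5.23 CPM, and SDHB, a subunit of complex II, rose 1.85-fold.

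Cholesterol synthesis genes fell in 20 of 24 cases, with 2 higher and 2 not passed (20 and 2 adjusted over the list alone, median -0.49). By camera the cholesterol list had adjusted p = 3.0e-05, and adjusted p = 0.362 with an estimated correlation. INSIG1, a sterol sensor of the endoplasmic reticulum, fell 2.53-fold from 681.9 ± 16.4 CPM. Some single genes of other lists fell much further. CP, encoding the copper-binding ferroxidase ceruloplasmin, fell 233.6-fold from 226.4 ± 5.73 CPM. NUPR1, a stress-response regulator, fell 278.3-fold from 97.4 ± 3.17 CPM, and PPARGC1A, a coactivator of mitochondrial gene expression, fell 241.5-fold from 45.0 ± 1.24 CPM. VEGFA, the main endothelial growth factor, fell 6.01-fold from 739.5 ± 15.7 to 122.9 ± 0.114 CPM.

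Genes regulated by p53 rose in 22 of 28 cases, with 3 lower and 3 not passed (23 and 3 adjusted over the list alone, median 0.66). By camera the p53-regulated list had adjusted p = 3.2e-06, and adjusted p = 0.274 with an estimated correlation. GADD45A, a growth arrest gene, rose from 38.9 ± 1.45 to 225.7 ± 5.82 CPM, and C12orf5, the older symbol of TIGAR, rose 5.21-fold. Of 30 NF-kB-regulated cytokines and regulators, 17 rose, 2 fell and 11 did not pass (17 and 2 adjusted over the list alone, median 1.30, 1.18 with bounds). By camera the NF-kB-regulated list had adjusted p = 3.0e-05, and adjusted p = 0.362 with an estimated correlation. IL8, a neutrophil chemokine, rose 7.34-fold to 21.9 ± 2.23 CPM, and CXCL2, a related chemokine, rose 10.7-fold to 6.58 ± 0.0273 CPM. Of 25 NRF2-regulated antioxidant genes, 17 rose, 4 fell and 4 did not pass (17 and 4 adjusted over the list alone, median 0.91, 0.82 with bounds). By camera the NRF2-regulated list had adjusted p = 0.000136, and adjusted p = 0.428 with an estimated correlation. SLC7A11, the cystine transporter, rose 6.45-fold from 16.2 ± 0.369 to 104.7 ± 7.35 CPM, whereas ABCC2, an export pump, fell 15.1-fold from 170.8 ± 4.13 CPM.

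Interferon-stimulated genes were higher in 28 of 41 cases, with 6 lower and 7 not passed (29 and 6 adjusted over the list alone, median 0.56). By camera the interferon list had adjusted p = 0.000439, and adjusted p = 0.725 with an estimated correlation. IFI6 rose 4.44-fold from 39.5 ± 2.71 to 176.1 ± 8.37 CPM, and XAF1 fell 4.61-fold. Ribosome assembly factors rose in 19 of 24 cases, with 2 lower and 3 not passed (19 and 2 adjusted over the list alone, median 0.63), RRP12 by 2.79-fold and NOLC1 by 2.11-fold. By camera the ribosome assembly list had adjusted p = 6.2e-06, and adjusted p = 0.362 with an estimated correlation. Of 19 genes of MHC class I presentation, 11 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone, median 0.39). By camera the MHC class I list had adjusted p = 0.00958, and adjusted p = 0.593 with an estimated correlation. CD274, which encodes the checkpoint ligand PD-L1 and was placed in that list, rose 7.84-fold from 4.66 ± 0.151 to 36.5 ± 2.69 CPM. The MHC class I call was lost after correction for GC content and length (adjusted p = 0.0662), although its median was still 0.38.

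Amino acid and stress genes regulated by ATF4 rose in 16 of 31 cases, with 6 lower and 9 not passed (16 and 7 adjusted over the list alone, median 0.61, 0.49 with bounds). By camera the ATF4-regulated list had adjusted p = 0.0314, and adjusted p = 0.362 with an estimated correlation. ATF3, a stress-induced transcription factor, rose 7.03-fold, whereas DDIT4, an inhibitor of mTORC1 signalling, fell 7.22-fold from 952.8 ± 11.1 CPM. Of 57 cytosolic ribosomal protein genes, 27 rose, 6 fell and 24 did not pass (27 and 6 adjusted over the list alone, median 0.13), and many of these genes share sequence with processed pseudogenes. By camera the ribosomal protein list had adjusted p = 0.0163, and adjusted p = 0.725 with an estimated correlation. Both calls were lost without double-knockout replicate 1 (adjusted p = 0.0590 and 0.0546) and after the correction for GC content and length (adjusted p = 0.0820 and 0.906), which left the ATF4-regulated median at 0.53 and the ribosomal one at -0.01. Quantile normalization (adjusted p = 0.0928 and 0.192) and the filter on low expression (adjusted p = 0.417 and 0.151) also ended both, and the pairwise fit ended the ATF4-regulated call (adjusted p = 0.372).

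The remaining lists were not called in the reported fit of this comparison, although collagen-modifying enzymes, mesenchymal markers, S phase genes, oxygen-sensing components and histones were under at least 1 alternative. For angiogenic factors 8 rose and 6 fell of 19, for the tricarboxylic acid cycle 10 and 6 of 25, for fatty acid oxidation 7 and 11 of 26, for lipid storage 5 and 7 of 20, for matrix proteins 7 and 14 of 31, and for collagen-modifying enzymes 5 and 8 of 18. LOX, the collagen and elastin crosslinking enzyme, fell 5.11-fold from 352 ± 7.74 CPM and PLOD2, a collagen lysyl hydroxylase, fell 6.77-fold from 530.2 ± 18.5 CPM. For mesenchymal markers 5 rose and 7 fell of 15, for epithelial junction genes 8 and 10 of 21, for renal tubule genes 5 and 4 of 18, for S phase genes 20 and 9 of 36, and for mitotic genes 11 and 9 of 36. CDH1, encoding E-cadherin, was at least 65.1-fold lower, from 3.55 ± 0.0309 CPM to no count, CDH16, a kidney cadherin, fell 17.5-fold, and CLDN1, a tight junction protein, rose 11.3-fold from 28.6 ± 0.851 to 323.7 ± 13.8 CPM. For endoplasmic reticulum chaperones 10 rose and 7 fell of 22, for iron handling 6 and 7 of 17, for oxygen-sensing components 6 and 6 of 15, for chromatin dioxygenases 5 and 10 of 21, for replication-dependent histones 8 and 0 of 19, and for reference genes 6 and 3 of 13. Adjusted over the list alone, these counts moved by at most 1 gene in either direction. The collagen-modifying list had a median of 0.12 but a mean of -0.23, the angiogenic list 0.02 and -0.39, and the lipid storage list 0.10 and -0.06. Their summaries therefore differ in sign.

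Markers of other cell types were not called as lists in any comparison. Leukocyte markers rose in 2 and fell in 1 of 13 in both comparisons with parental cells, endothelial markers in 1 and 1 of 8 for double-knockout and 2 and 1 of 8 for VHL-restored cells, and fibroblast markers in 2 and 2 of 10 and 3 and 1 of 10. Between the engineered lines 2 leukocyte markers were higher and 2 lower, 1 and 2 endothelial markers, and 1 and 3 fibroblast markers. CD68, a lysosomal protein of macrophages that tumour cells also make, had the highest level of the leukocyte markers and fell from 62.4 ± 2.98 CPM in parental to 21.5 ± 0.917 in double-knockout and 24.6 ± 2.00 in VHL-restored cells.

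**Figure D2:**
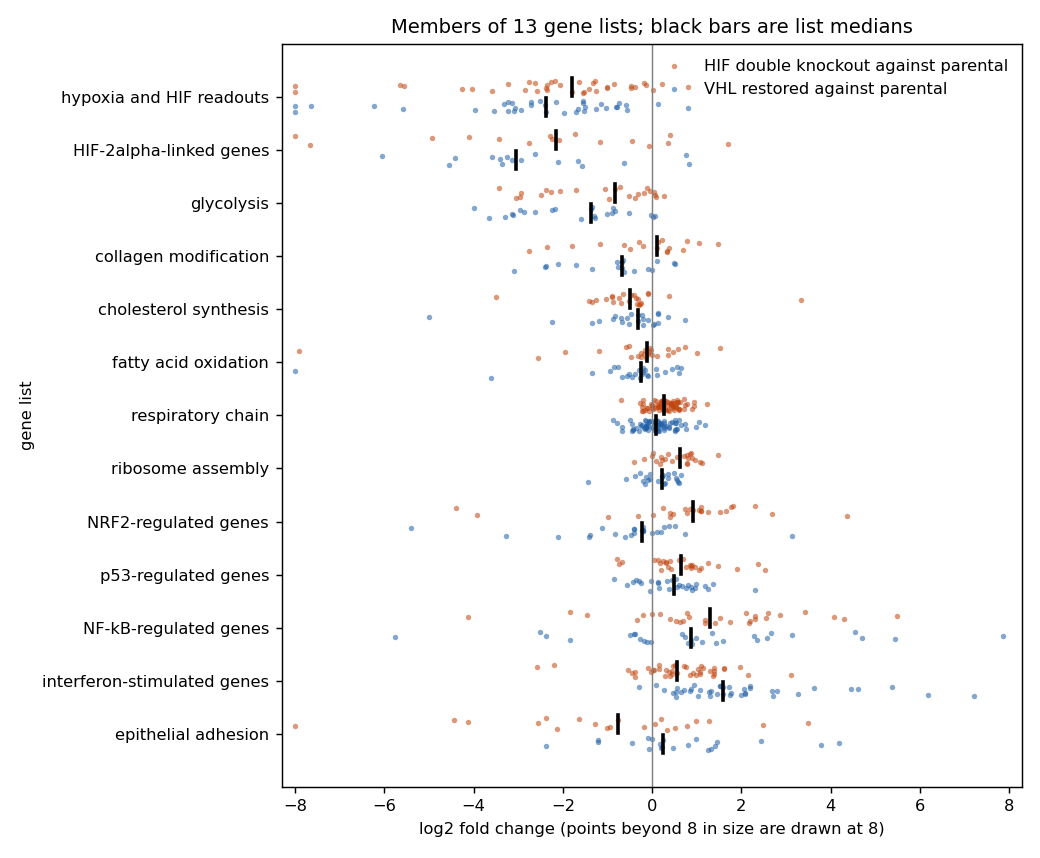
Log2 fold change of each member of 13 gene lists in double-knockout and VHL-restored cells against parental cells, with black bars at the list medians. The hypoxia medians are -1.80 and -2.37, and the interferon medians 0.56 and 1.58.

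In all, 9888 of 18273 genes (54.1%) passed an adjusted p of 0.05 in double-knockout cells by edgeR, 4858 higher and 5030 lower, and 1107 and 1875 of these changed at least 2-fold. Centring each library on its median gave 6005 higher and 4133 lower, so the balance between directions rested on the scaling. Without any 1 library the count was between 7974 and 10134. Gene lists were called in 13 of 33 tests by camera, and in 0 with an estimated correlation, where the smallest adjusted p was 0.274.

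The comparison of VHL-restored with parental cells asked what differed after VHL was reintroduced, again without an empty-vector control. EGLN3 fell 2079-fold, from 418 ± 0.478 to 0.197 ± 0.177 CPM (n = 2), and NDRG1 fell 74.8-fold to 24.2 ± 0.270 CPM. CA12, a membrane carbonic anhydrase, fell 200.5-fold from 459.6 ± 17.7 to 2.29 ± 0.251 CPM. STC1 again had no count, at least 505-fold lower than in parental cells, and CP fell 482.2-fold. Interferon-stimulated genes rose: OAS2, an antiviral oligoadenylate synthetase, rose 147.9-fold from 0.578 ± 0.0553 to 85.5 ± 7.45 CPM, and RSAD2, the antiviral protein viperin, rose 24.5-fold to 54.3 ± 3.60 CPM.

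Of the 37 hypoxia readouts, 34 fell, 1 rose and 2 did not pass (34 and 2 adjusted over the list alone, median log2 fold change -2.37, -2.28 with bounds). By camera the hypoxia list had adjusted p = 1.3e-20, and adjusted p = 0.0684 with an estimated correlation. Of the 16 genes linked to HIF-2alpha, 14 fell, 0 rose and 2 did not pass (14 and 0 adjusted over the list alone, median -3.04, -3.15 with bounds). By camera the HIF-2alpha-linked list had adjusted p = 2.3e-10, and adjusted p = 0.329 with an estimated correlation. EDN1, encoding the vasoconstrictor endothelin, fell 23.4-fold from 4.72 CPM, and TGFBI, a secreted matrix protein, fell 12.1-fold from 1290 ± 35.5 CPM. Of the 23 glycolysis genes, 20 fell, 0 rose and 3 did not pass (20 and 0 adjusted over the list alone, median -1.37). By camera the glycolysis list had adjusted p = 3.6e-14, and adjusted p = 0.329 with an estimated correlation. SLC2A3 fell 15.8-fold and ALDOC 12.5-fold.

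Of the 41 interferon-stimulated genes, 38 rose, 0 fell and 3 did not pass (38 and 0 adjusted over the list alone, median 1.58). By camera the interferon list had adjusted p = 1.3e-18, and adjusted p = 0.329 with an estimated correlation. OASL, a relative of OAS2, rose 72.6-fold to 43.3 ± 0.526 CPM, and IFITM1, a membrane protein that blocks viral entry, rose 41.4-fold to 8.88 ± 1.64 CPM. The leukocyte marker with the highest level, CD68, fell 2.54-fold in the same libraries. MHC class I genes were not called as a list, with 5 higher and 10 lower of 19, although CD274 rose 8.33-fold to 38.7 ± 0.836 CPM. NF-kB-regulated genes rose in 15 of 30 cases, with 5 lower and 10 not passed (15 and 5 adjusted over the list alone, median 0.88, 0.87 with bounds). By camera the NF-kB-regulated list had adjusted p = 0.00664, and adjusted p = 0.329 with an estimated correlation. TNF, a proinflammatory cytokine gene, went from no count to 1.07 ± 0.304 CPM, at least 18.7-fold higher, whereas CCL20, a chemokine gene, went from 3.17 ± 0.438 to 0.0536 CPM, a ratio of 58.4 with a counting interval of 19.6 to 286.

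Epithelial junction genes rose in 14 of 21 cases, with 3 lower and 4 not passed (14 and 3 adjusted over the list alone, median 0.25, 0.36 with bounds). By camera the epithelial list had adjusted p = 0.0114, and adjusted p = 0.329 with an estimated correlation. KRT7, a simple-epithelial keratin, rose 18.2-fold from 0.624 ± 0.0711 to 11.5 ± 1.23 CPM, and CLDN1 rose 13.7-fold to 392.4 ± 12.9 CPM. Mesenchymal markers fell in 8 of 15 cases, with 2 higher and 5 not passed (8 and 2 adjusted over the list alone, median -0.25). By camera the mesenchymal list had adjusted p = 0.0473, and adjusted p = 0.528 with an estimated correlation. FN1 was one of the members that rose, 3.07-fold, and its call was lost under quantile normalization, where the gene with the most counts takes the same value in every library. The epithelial call was lost without parental replicate 2 (adjusted p = 0.0612) and under the chromosomal neighbourhood correction (adjusted p = 0.0621), where its median was 0.33 and so no smaller. The mesenchymal call was lost without parental replicate 1, double-knockout replicate 1, double-knockout replicate 2 or VHL-restored replicate 2, with adjusted p between 0.0963 and 0.104. It was also lost with median-ratio size factors, quantile normalization, median centring, log2(CPM + 1), limma on log2 CPM and the replicate block, with adjusted p between 0.0501 and 0.0815.

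Collagen-modifying enzymes fell in 11 of 18 cases, with 1 higher and 6 not passed (11 and 1 adjusted over the list alone, median -0.68, -0.67 with bounds). By camera the collagen modification list had adjusted p = 0.000357, and adjusted p = 0.329 with an estimated correlation. LOX fell 8.52-fold, P4HA1, a collagen prolyl hydroxylase, fell 5.31-fold, and LOXL2, a LOX relative, fell 4.29-fold from 852.9 ± 19.4 CPM. The matrix list itself was not called, with 9 higher and 11 lower of 31. In it COL5A1, a fibrillar collagen, went from 100.2 ± 1.93 to 0.0358 CPM, a ratio of 2798 with a counting interval of 774 to 23110, while LAMA5, a basement membrane laminin, rose 5.52-fold to 500.4 ± 78.1 CPM.

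Lipid lists fell as well. Fatty acid oxidation genes fell in 16 of 26 cases, with 4 higher and 6 not passed (16 and 4 adjusted over the list alone, median -0.26), and ACAA2, a mitochondrial thiolase, fell 12.3-fold from 33.2 ± 0.531 CPM. By camera the fatty acid oxidation list had adjusted p = 0.0139, and adjusted p = 0.329 with an estimated correlation. That call was lost with the filter on low expression (adjusted p = 0.172). Lipid storage genes fell in 10 of 20 cases, with 2 higher and 8 not passed (11 and 2 adjusted over the list alone, median -0.56, -0.37 with bounds), and PLIN2 fell 10.3-fold. By camera the lipid storage list had adjusted p = 0.0304, and adjusted p = 0.329 with an estimated correlation. Cholesterol synthesis genes fell in 16 of 24 cases, with 3 higher and 5 not passed (16 and 3 adjusted over the list alone, median -0.31), INSIG1 by 4.72-fold. By camera the cholesterol list had adjusted p = 0.00664, and adjusted p = 0.422 with an estimated correlation. NRF2-regulated genes fell in 17 of 25 cases, with 4 higher and 4 not passed (17 and 4 adjusted over the list alone, median -0.22, -0.39 with bounds). By camera the NRF2-regulated list had adjusted p = 0.00641, and adjusted p = 0.527 with an estimated correlation. ABCC2 fell 42.1-fold and AKR1B10, an aldo-keto reductase, fell 9.65-fold to 1.16 ± 0.126 CPM.

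S phase genes rose in 22 of 36 cases, with 8 lower and 6 not passed (22 and 8 adjusted over the list alone, median 0.39), and MCM3, a subunit of the replicative helicase, rose 2.27-fold from 222.3 ± 11.9 to 504.1 ± 7.82 CPM. By camera the S phase list had adjusted p = 0.00641, and adjusted p = 0.391 with an estimated correlation. Mitotic genes were not called, with 8 higher and 12 lower of 36. Genes regulated by p53 rose in 19 of 28 cases, with 6 lower and 3 not passed (19 and 6 adjusted over the list alone, median 0.50), C12orf5 by 4.94-fold. By camera the p53-regulated list had adjusted p = 0.000811, and adjusted p = 0.329 with an estimated correlation. Ribosomal protein genes rose in 35 of 57 cases, with 4 lower and 18 not passed (36 and 4 adjusted over the list alone, median 0.21). By camera the ribosomal protein list had adjusted p = 5.7e-05, and adjusted p = 0.731 with an estimated correlation. The remaining lists were not called in the reported fit, although mitotic genes, ATF4-regulated genes, chaperones and iron handling were under at least 1 alternative. Angiogenic factors had 6 higher and 8 lower of 19, respiratory chain genes 28 and 16 of 74, the tricarboxylic acid cycle 5 and 10 of 25, renal tubule genes 2 and 6 of 18, and ATF4-regulated genes 11 and 15 of 31. Chaperones of the endoplasmic reticulum had 7 higher and 10 lower of 22, iron handling 6 and 8 of 17, oxygen-sensing components 5 and 5 of 15, chromatin dioxygenases 5 and 7 of 21, ribosome assembly factors 14 and 6 of 24, histones 1 and 6 of 19, and reference genes 2 and 6 of 13. When adjusted over the list alone, the counts of uncalled lists moved by at most 1 gene. Medians and means differed in sign for MHC class I genes (-0.19 and 0.23), oxygen-sensing components (0.06 and -0.49) and histones (-0.10 and 0.21). The same held for chromatin dioxygenases (0.04 and -0.14) and renal tubule genes (-0.05 and 0.20). Without VHL-restored replicate 1 the respiratory chain list was called higher (adjusted p = 0.0159).

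In VHL-restored cells 9898 genes (54.2%) passed an adjusted p of 0.05 by edgeR, 4843 higher and 5055 lower, with 1121 and 1535 at least 2-fold. Median centring gave 5571 higher and 4364 lower. Camera called 15 of 33 lists, and 0 with an estimated correlation (smallest adjusted p = 0.0684).

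Both engineered lines were set against the same parental libraries. Changes in the same direction were found for 5381 genes, 2834 lower in both and 2547 higher in both, and changes in opposite directions for 1766 genes. Independent lists of these sizes would share 1391 lower and 1288 higher genes and hold 2677 in opposite directions. These numbers take each of the 18273 tested genes as equally likely to be called. Genes with few counts are seldom called in either comparison, so these numbers are too low and the excess in the same direction is overstated. EGLN3, NDRG1, STC1, CP and IGFBP3 were among the genes lower in both by at least 2-fold, of which there were 841, against 391 higher in both by at least 2-fold, CLDN1 and CD274 among them. In 20 simulations of unchanged groups, with all 6 libraries drawn anew from the parental means, edgeR called 0 genes the same way. As no gene was changed in them, that 0 is no benchmark for the 5381. Over 11785 genes with a mean log2 CPM of at least 1, the fold changes had a Pearson r of 0.498 and a Spearman rho of 0.432 across genes, which are not independent replicates. The simulated r was 0.509 from the shared controls alone, and 67.1% of genes had the same sign in the simulations against 64.8% observed. Unchanged groups with shared controls give values of this size whatever the amount of noise, so neither measure can separate shared change from shared controls. The covariance was 0.407 observed against 0.00516 ± 0.000122 simulated (SD), a difference of 0.401. This difference argues against the spread between the parental libraries as the source of most of the agreement in fold changes. That spread may be technical, and the simulations hold no difference between parental cultures. The controls are too few to split into parts of at least 2 libraries. A smaller part of the excess of shared calls may therefore still come from the shared controls.

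**Figure D3:**
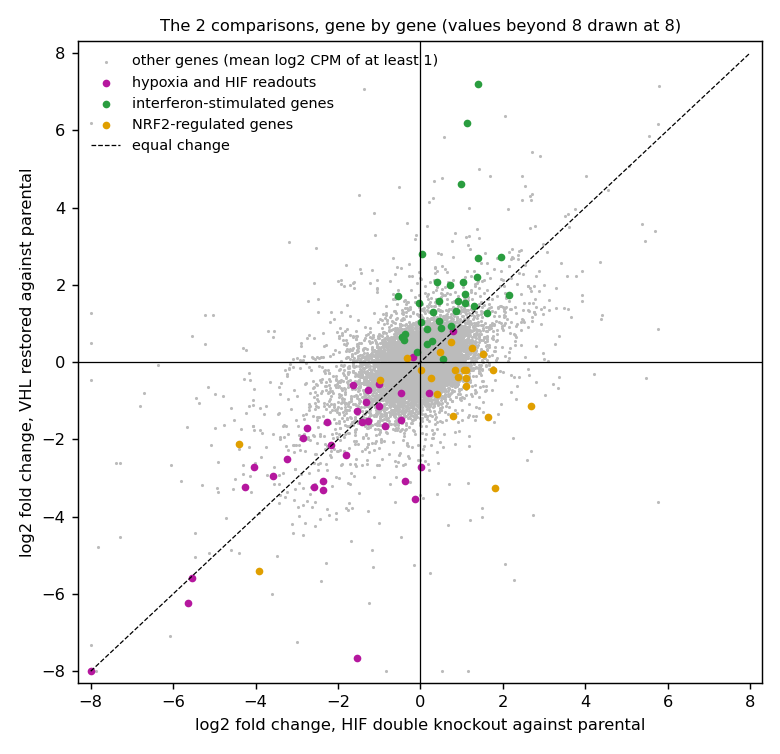
Log2 fold change of each gene with a mean log2 CPM of at least 1 in double-knockout (horizontal) and VHL-restored cells (vertical) against parental cells, with hypoxia, interferon and NRF2 lists coloured. Fold changes beyond 8 are drawn at 8.

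The direct comparison of double-knockout with VHL-restored cells tested where the engineered lines differed. The parental libraries cancel out of its fold changes but still enter its estimate of spread. HIF1A was 9.65-fold and EPAS1 7.93-fold lower in double-knockout cells, and VHL was 15.2-fold lower. CA12 was 69.2-fold higher in double-knockout (158.7 ± 5.10 CPM) than in VHL-restored cells (2.29 ± 0.251 CPM, n = 2). STC2, a stanniocalcin relative of STC1, was 10.6-fold higher. IL6 was 59.7-fold higher, and SERPINB2 had a ratio of 21520 with a counting interval of 3863 to 850200. CDH1 was at least 155-fold lower in double-knockout cells, with no count against 8.44 ± 0.107 CPM. Of the 37 hypoxia readouts 16 were higher, 13 lower and 8 not passed (17 and 13 adjusted over the list alone, median 0.14) with a camera adjusted p = 0.329, and of the 16 genes linked to HIF-2alpha 6 were higher, 4 lower and 6 not passed (6 and 4 adjusted over the list alone, median 0.14, 0.35 with bounds) with a camera adjusted p = 0.492.

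Of the 41 interferon-stimulated genes, 35 were lower in double-knockout cells, 3 higher and 3 not passed (37 and 3 adjusted over the list alone, median -1.02). By camera the interferon list had adjusted p = 2.8e-10, and adjusted p = 0.413 with an estimated correlation. OAS2 was 56.4-fold lower. Of the 25 NRF2-regulated genes, 19 were higher, 3 lower and 3 not passed (19 and 3 adjusted over the list alone, median 1.27, 1.25 with bounds). By camera the NRF2-regulated list had adjusted p = 2.5e-06, and adjusted p = 0.413 with an estimated correlation. AKR1B10 was 34.1-fold higher, SLC7A11 14.1-fold and HMOX1, the heme-degrading oxygenase, 3.91-fold. Of the 23 glycolysis genes, 14 were higher, 1 lower and 8 not passed (15 and 1 adjusted over the list alone, median 0.55), with HK1, a hexokinase, 4.99-fold higher. By camera the glycolysis list had adjusted p = 5.8e-05, and adjusted p = 0.533 with an estimated correlation. Epithelial junction genes were lower in 16 of 21 cases, with 3 higher and 2 not passed (16 and 3 adjusted over the list alone, median -1.01, -1.10 with bounds), and EPCAM, an epithelial adhesion molecule, was 5.10-fold lower. By camera the epithelial list had adjusted p = 0.000370, and adjusted p = 0.413 with an estimated correlation.

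MHC class I genes were higher in 15 of 19 cases, with 1 lower and 3 not passed (15 and 1 adjusted over the list alone, median 0.39, 0.40 with bounds). By camera the MHC class I list had adjusted p = 0.000274, and adjusted p = 0.413 with an estimated correlation. B2M, the invariant light chain, was 2.17-fold higher. Ribosome assembly factors were higher in 18 of 24 cases, with 1 lower and 5 not passed (18 and 3 adjusted over the list alone, median 0.49), the transcription factor gene MYC by 2.05-fold. By camera the ribosome assembly list had adjusted p = 8.7e-05, and adjusted p = 0.413 with an estimated correlation. ATF4-regulated genes were higher in 20 of 31 cases, with 5 lower and 6 not passed (20 and 5 adjusted over the list alone, median 0.60, 0.54 with bounds), whereas NUPR1 was 200.3-fold lower. By camera the ATF4-regulated list had adjusted p = 0.000486, and adjusted p = 0.413 with an estimated correlation. Collagen-modifying enzymes were higher in 13 of 18 cases, with 2 lower and 3 not passed (13 and 2 adjusted over the list alone, median 0.54), PLOD3, a lysyl hydroxylase, by 2.74-fold. By camera the collagen modification list had adjusted p = 0.00167, and adjusted p = 0.413 with an estimated correlation.

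Respiratory chain genes were higher in 40 of 74 cases, with 14 lower and 20 not passed (42 and 14 adjusted over the list alone). By camera the respiratory chain list had adjusted p = 0.00264, and adjusted p = 0.686 with an estimated correlation. Chaperones of the endoplasmic reticulum were higher in 14 of 22 cases, with 3 lower and 5 not passed (14 and 3 adjusted over the list alone), CRELD2, a secreted chaperone, by 1.96-fold. By camera the chaperone list had adjusted p = 0.0217, and adjusted p = 0.413 with an estimated correlation. Both calls were lost under quantile normalization (adjusted p = 0.0888 for each) and with the filter on low expression (adjusted p = 0.0970 and 0.157), and the respiratory chain call also after the GC and length correction (adjusted p = 0.169, median 0.12 in place of 0.21). Angiogenic factors were higher in 9 of 19 cases, with 3 lower and 7 not passed (9 and 3 adjusted over the list alone), with EDN1 17.2-fold higher. By camera the angiogenic list had adjusted p = 0.0498, and adjusted p = 0.532 with an estimated correlation. Reference genes were higher in 8 of 13 cases, with 2 lower and 3 not passed (8 and 2 adjusted over the list alone), ACTB by 1.72-fold. By camera the reference gene list had adjusted p = 0.0237, and adjusted p = 0.413 with an estimated correlation. Leaving out any 1 of the parental or double-knockout libraries ended both of these calls, and leaving out VHL-restored replicate 2 ended the angiogenic call, with adjusted p between 0.0537 and 0.0975. Both also ended under quantile normalization (adjusted p = 0.153 and 0.149), log2(CPM + 1) (0.0606 and 0.0554), limma on log2 CPM (0.0793 and 0.0637) and the neighbourhood correction (0.560 and 0.120), which left medians of 0.08 and 0.04. The angiogenic call ended as well with the low-expression filter (adjusted p = 0.117), the GC and length correction (0.0867, median 0.33 in place of 0.41), the replicate block (0.0559), the pairwise fit (0.0513) and median-ratio size factors (0.0509).

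For the lists not called between the engineered lines, the tricarboxylic acid cycle had 13 higher and 5 lower of 25, fatty acid oxidation 15 and 6 of 26, lipid storage 5 and 5 of 20, cholesterol synthesis 6 and 10 of 24, matrix proteins 9 and 9 of 31, and mesenchymal markers 9 and 5 of 15. Renal tubule genes had 4 higher and 3 lower of 18, S phase genes 10 and 16 of 36, mitotic genes 14 and 7 of 36, p53-regulated genes 15 and 8 of 28, and NF-kB-regulated genes 13 and 8 of 30. Iron handling had 9 higher and 5 lower of 17, oxygen-sensing components 6 and 5 of 15, chromatin dioxygenases 4 and 9 of 21, ribosomal proteins 6 and 22 of 57, and histones 7 and 1 of 19. Counts adjusted over the list alone moved by at most 1 gene, apart from iron handling with 9 higher and 7 lower. For mesenchymal markers the median was 0.57 and the mean -0.09, for oxygen-sensing components 0.31 and -0.36, for iron handling 0.27 and -0.06, and for renal tubule genes 0.01 and -0.30. The ribosomal protein list was called lower without VHL-restored replicate 1 (adjusted p = 0.000114), under quantile normalization (0.00738) and after the GC and length correction (0.000473). Cholesterol synthesis, renal tubule, p53-regulated and NF-kB-regulated genes, oxygen-sensing components and histones were also called under at least 1 alternative. In total 10225 genes (56%) differed by edgeR, 5113 higher and 5112 lower in double-knockout cells, and 12 of 33 lists were called by camera, 0 of them with an estimated correlation.

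Neighbouring genes moved together in both engineered lines, over whole chromosomes or parts of them. In VHL-restored cells the median log2 fold change was -0.59 over the 511 expressed genes of chromosome 7, 90.4% of them lower, -0.60 over the 108 of chromosome 21, 0.43 over the 587 of chromosome 12 and 0.40 over the 745 of chromosome 19. In double-knockout cells the medians of whole chromosomes were smaller, from -0.18 on chromosome 7 to 0.27 on chromosome 22, but parts of chromosomes moved apart. Medians of blocks of up to 40 neighbouring genes were taken after the correction for GC content and length, unlike the whole-chromosome medians above. Of the blocks in double-knockout cells, 6 of 9 on chromosome 14 were higher and 3 lower, and those on chromosome 9 ran from -0.52 to 0.12. In VHL-restored cells all 13 blocks of chromosome 7 were lower, whereas those of chromosome 16 ran from -0.48 to 0.37. After each gene's chromosomal neighbourhood was subtracted, an alternative chosen after seeing the data, the hypoxia readouts had medians of -1.81 and -2.01 in double-knockout and VHL-restored cells, and the interferon list 1.71 in VHL-restored cells. PLIN2 was 1.68-fold lower in double-knockout than in VHL-restored cells, and its direction turned under that correction, to 0.21 on the log2 scale.

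**Figure D4:**
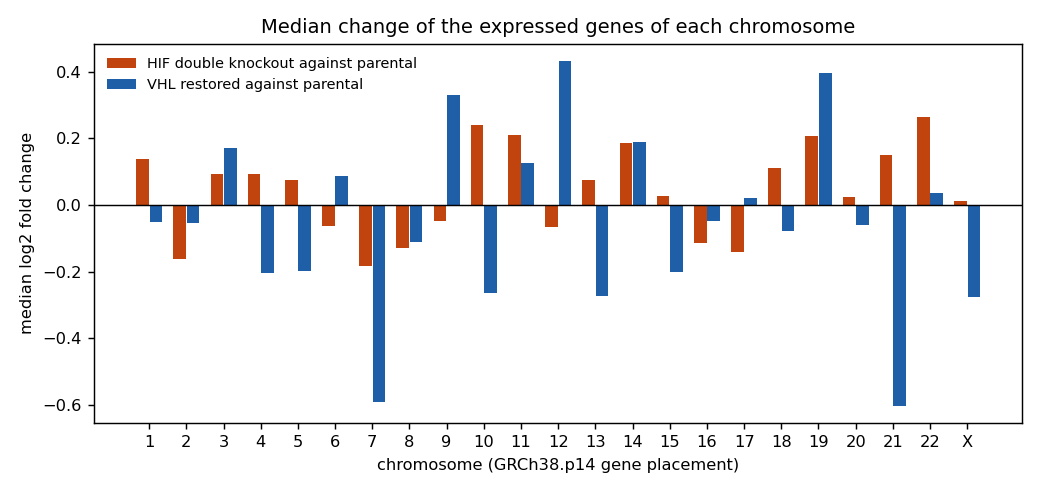
Median log2 fold change of the expressed genes of each chromosome for both comparisons with parental cells. Chromosomes 7 and 21 lie at -0.59 and -0.60 in VHL-restored cells, and chromosome 12 at 0.43.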

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

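The tests of leukocyte content, of an equal response to transduction, of extra copies around HIF1A and of a library swap were chosen only after the results were seen, and so was the choice to examine chromosomes, while the GC, copy number and scaling tests were set out before their results.

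HIF1A mRNA moved in opposite directions in the engineered lines, and the direct test of their difference gave -3.27 on the log2 scale (double knockout minus VHL-restored, lower in both double-knockout libraries than in both VHL-restored libraries). In VHL-restored cells it was higher than in parental cells under each scaling tried, with a lowest log2 fold change of 2.05, which argues against scaling. The 20 nearest expressed genes had a median of -0.42 (from -1.1 to 0.79), which argues against a gain of the whole region, although a gain of HIF1A alone stays open. VHL was at least 16.6 times the parental mean in both VHL-restored libraries and at most 1.21 times in the others, so a swap of libraries between groups is not borne out. A feedback on HIF1A transcription after VHL return, a clone or population that differs in HIF1A, and an effect of the vector may each account for it, and were not tested.

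The median of the 25 NRF2-regulated genes also differed between the engineered lines, at 1.27 on the log2 scale by the direct comparison, higher in double-knockout and lower in VHL-restored than in parental cells. No explanation was tested for this list, and AKR1C genes in it share sequence.

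Interferon-stimulated genes were higher in VHL-restored than in parental cells, 38 of 41 of them. After the correction for GC content and length their median was 1.56, which argues against that trend as the whole cause. The leukocyte markers had a median of at most 0.143 CPM in either VHL-restored library, and of 13 markers 2 exceeded 1 CPM, CD68 at 24.6 and CSF1R at 1.04, so leukocytes are an unlikely source. The list was lower in double-knockout than in VHL-restored cells by a median of -1.02, with 38 of 41 genes differing, so an equal response to lentivirus in both lines cannot account for all of it. The list was also higher in double-knockout than in parental cells, with 28 genes higher, 6 lower and a median of 0.56. A part common to both engineered lines, from reduced HIF activity or from lentivirus, was not tested and stays open. A response to this vector or to the VHL transcript itself, VHL acting without HIF, and a chance difference between cell populations also stay open as hypotheses.

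Genes of whole chromosomes, or of large parts of them, shifted together in both comparisons with parental cells. After the GC and length correction the chromosome medians still had an SD of 0.144 in double-knockout and 0.257 in VHL-restored cells (0.136 and 0.266 before), against at most 0.0612 and 0.0537 when 1000 random placements of genes were drawn, which argues against that bias. Chromosome medians from weakly and strongly expressed genes followed each other, with r = 0.683 and 0.963 over 23 chromosomes. Copy number differences between the populations of cells are therefore a candidate explanation, strongest for chromosomes 7, 12, 19 and 21 in VHL-restored cells, and no DNA measurement was available to test it directly. Populations grown from few cells could differ in this way, and such differences may then underlie part of the changes listed for single genes.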

How the results depend on the processing

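The median-ratio size factors, the limma fit on log2 CPM, the GC and length correction and the neighbourhood correction were chosen after seeing the data, and the other alternatives were chosen before the data were examined.

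Counts of changed genes stayed within 1.5 times the reported ones under each alternative other than the 2-fold threshold. With all libraries and without that threshold, those for double knockout against parental cells ran from 8721 with the low-expression filter, where fewer genes are tested, to 10514 with the GC and length correction. DESeq2 gave 8830, 8660 and 9053 in the 3 comparisons and 4625 changed the same way. The DESeq2 calls shared 8815, 8646 and 9040 genes with the reported ones, each with the same direction. Under the neighbourhood correction the shared calls were fewer, 8421, 7649 and 8181, of which 8355, 7394 and 7921 had the same direction. Median centring moved the median of all genes from 0 to 0.07 and 0.05 in the comparisons with parental cells and changed the balance, to 6005 higher and 4133 lower in double-knockout and 5571 and 4364 in VHL-restored cells. Genes with few counts hold that median near 0, and expressed genes moved further. The S phase median in double-knockout cells went from 0.25 to 0.38, and the mesenchymal median in VHL-restored cells from -0.25 to -0.17. A change of at least 2-fold was met by 2982 genes in double-knockout and 2656 in VHL-restored cells against parental cells, by 3038 between the engineered lines, and by 1232 in the same direction in both, a smaller number by construction.

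With 1 library left out at a time, between 7974 and 10134 genes changed in double-knockout cells, between 7891 and 9671 in VHL-restored cells, between 9019 and 9679 between the engineered lines, and between 3989 and 5300 the same way. The lists called ran from 11 to 13, from 14 to 16 and from 10 to 13. In these fits the lone library of a group is assumed to vary like the other groups.

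Camera with an estimated correlation called 0 lists in double-knockout cells (smallest adjusted p = 0.274), 0 in VHL-restored cells (0.0684) and 0 between the engineered lines (0.413), against 13, 15 and 12 with the preset correlation, while fry, which tests each list without comparing it with other genes, called 26, 25 and 29. The estimate lets members of a list vary together, but a larger correlation cannot explain each lost call. For the hypoxia list in VHL-restored cells the estimate was 0.007, below the preset 0.01, yet the camera adjusted p went from 1.3e-20 to 0.0684. For epithelial junction genes in those cells it was -0.0255, and the camera adjusted p went from 0.0114 to 0.329. Some called lists had large estimates, such as 0.87 for ribosomal proteins in those cells. With an estimated correlation camera also relies on the residual degrees of freedom of the fit, which are few with 6 libraries in 3 groups. That raises its p-values even where the estimated correlation is small. How much of each lost call this accounts for was not tested. Camera was not run with DESeq2, which gives no camera fit.

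Adding replicate number as a block gave 10112, 10148 and 10458 changed genes, 5592 the same way, and 13, 14 and 11 lists. Replicate differences correlated at 0.187, -0.0131 and 0.0256 between groups, so the shared numbers show little sign of pairing.

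Apart from the estimated correlation, 72 of 99 list results and 376 of 423 named gene results kept their side of the threshold under each alternative run. Among these, results called in the reported fit, as 40 of the 99 list results were, also kept their direction. Of the 423 named gene results 422 were called in that fit, most of them chosen from it for large changes, so they were likely to stay called. The low-expression filter tested only 303 of the 423, and a result it dropped was not counted as moved. Where neither fit called a result, its direction was not compared. Among results called in at least 1 of the 2 fits compared, the neighbourhood correction turned 2 directions in VHL-restored cells. These were of the mitotic list (0.0760 in place of -0.04) and of KDM5A (-0.0913 in place of 0.59). Between the engineered lines it turned PLIN2 (0.21 in place of -0.75) and KDM4C (0.0803 in place of -0.79). That correction removes the median of each gene's neighbours by construction. For other calls lost the cause was not tested.

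Some lists not called in the reported fit were called under an alternative. In double-knockout against parental cells these were histones with quantile normalization (adjusted p = 0.0241), the low-expression filter (0.0400) and the neighbourhood correction (0.00673). Collagen modification was called lower by camera with the filter (adjusted p = 0.0118, median -0.19) and the pairwise fit (0.00817, median 0.12). Oxygen sensing was also called lower with the filter (0.0118, median 0.04) and the pairwise fit (0.00324, median -0.03). Mesenchymal markers were called with the pairwise fit (0.0357) and S phase genes with median centring (0.0373). In VHL-restored against parental cells the neighbourhood correction called the mitotic list, with its direction turned, and the chaperone list (0.0383 each) and the ATF4-regulated list (0.0496). The filter called the ATF4-regulated (0.00297) and iron handling (0.0137) lists there. Between the engineered lines the filter called NF-kB-regulated genes (0.00118), histones (0.00208), oxygen sensing (0.00382) and renal tubule genes (0.0297), and the neighbourhood correction called p53-regulated genes (0.00982), histones (0.00995) and cholesterol synthesis (0.0365).

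Depth limits genes with few counts. In simulated changes of 2-fold, 100 genes for each range of level, 6% were recovered under 1 CPM, 92% from 1 to 10 CPM and 100% above in double-knockout against parental cells. The ranges were chosen after seeing the data. In other simulated changes of 1.2-fold, 14% were recovered in double-knockout cells, and at 2-fold 98%, so small changes are missed more often than large ones. Both simulations changed far fewer genes than were called in the data, so their shares may understate recovery there.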

Other observations

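The on and off pattern and the gene families described here were chosen only after the results were seen, and none of these tests was planned.

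A few genes were on in every library of some groups and had at most 3 counts in another. PDCD1LG2, which encodes the checkpoint ligand PD-L2, was at 0.0389 ± 0.00736 CPM in parental cells and at 6.70 ± 0.526 and 6.17 ± 0.274 CPM in double-knockout and VHL-restored cells (n = 2 each). ENPP3, an ectonucleotide pyrophosphatase, ITIH5, a hyaluronan-binding protein, and MYH13, a muscle myosin, were on in parental cells alone (5.52 ± 0.576, 7.68 ± 0.140 and 18.5 ± 1.06 CPM) and had no count in the engineered lines. SERPINB2 was on in double-knockout cells alone. In VHL-restored cells GSG1L, a subunit of glutamate receptor complexes, stood at 21.2 ± 0.617 CPM, HHIP, a hedgehog-binding protein, at 11.2 ± 0.599 CPM, and MIR205, a microRNA locus, at 19.9 ± 1.22 CPM, with at most 3 counts elsewhere. COL5A1, CMBL, a hydrolase, FERMT1, an integrin activator, and APOBEC3G, a cytidine deaminase, were silent there alone.

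Families of genes that share the first letters of a symbol were also compared, 198 of them with at least 8 genes. Mitochondrial ribosomal proteins of the large subunit (MRPL) rose in 37 of 49 cases and fell in 3 in double-knockout cells, with a median of 0.41 (camera adjusted p = 1.5e-06, and adjusted p = 0.839 with an estimated correlation). Subunits of the mitochondrial inner membrane translocase (TIMM) rose in 12 of 13 cases, with a median of 0.61. UDP-glucuronosyltransferases (UGT), several of which share exons, fell in 10 of 11 cases in double-knockout and 11 of 11 in VHL-restored cells, with medians of -0.85 and -0.80. Of the 11, 9 lie on chromosome 2. The 2 elsewhere had medians of -0.83 and -0.29, with 1 and 2 of them lower. ADAMTS proteases rose in 9 of 11 cases in VHL-restored cells, with a median of 1.26. Zinc finger genes (ZNF) were lower in double-knockout than in VHL-restored cells in 232 of 431 cases and higher in 70, with a median of -0.32. Of these, 209 lie on chromosome 19, which was lower as a whole in that comparison, and had a median of -0.44, while the 222 on other chromosomes had a median of -0.12, so much of this shift may belong to the chromosome. Under the neighbourhood correction the zinc finger median was -0.18. None of these directions turned under median centring, quantile normalization, size factors or the neighbourhood correction, and none of the families held by camera with an estimated correlation (smallest adjusted p = 0.837).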
